A study of Mus musculus with 12 samples.

How the data were processed

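RNA sequencing of mouse bone-marrow-derived macrophages was analysed in 12 libraries, 3 per group, for control, LPS, tunicamycin and tunicamycin plus LPS. Per the labels the cells were grown with M-CSF for 7 days in medium with 10% serum, and tunicamycin (5 ug/ml) preceded LPS (1 ng/ml, 3 h) by 3 h. How long the cells with tunicamycin alone were exposed, and whether tunicamycin stayed during LPS, is not given in the sources used here. The values are the authors' deposited FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, with 1 value per gene symbol and library. Per the submitters' processing notes TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 were used on mm10; the gene annotation and any scaling between libraries are not given there. The table holds 24346 genes, 12 library columns that all match a sample, and no identical pair of libraries; 23310 symbols match GENCODE M21, from which the coordinates were taken. Read depth is unknown. Between control replicate 1 and each other library, 6.52% to 19% of genes below 0.3 FPKM in both lay within log2 0.02 of the most common ratio. Counts were not recovered from these low values, so the precision given is the spread between replicates. Summed FPKM per library was 561108 to 685010, while median-of-ratios factors were 1.012 to 1.017 in all 12 libraries. The deposited values were thus already level between libraries on that scale, by a step that the notes do not give.

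Genes with an FPKM of at least 1 in at least 3 libraries were kept (10311) and log2(FPKM + 1) was fitted with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, with 1 mean per group over all 12 libraries. There were 5 contrasts: LPS against control, tunicamycin against control, tunicamycin plus LPS against LPS and against tunicamycin, and the interaction, which is the LPS effect with tunicamycin less that without it. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. LPS-induced genes passed the first contrast with a log2 fold change of at least 1, and their numbers lower or higher with both agents are given beside 100 simulations with no tunicamycin effect. A factor common to a whole group, such as a change in total RNA per cell, cannot be seen in FPKM.

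Before the data were examined, 25 gene lists were fixed from general knowledge: ER chaperones, ATF4/CHOP stress response, N-glycosylation, cytokines and chemokines, NF-kB feedback and other LPS-response effectors, type I interferon response, TLR4 signalling, inflammasome, immediate early genes, glycolysis, cholesterol, NRF2, proliferation, apoptosis, autophagy and lysosome, homeostatic macrophage genes, antigen presentation, and markers of macrophages, neutrophils, stromal cells, dendritic cells, T and NK cells, B and plasma cells, erythroid cells and mast cells. The 20 lists with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated from the data. For each list the members that rose, fell and did not pass are counted, also with p adjusted over the list alone.

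The genes named were set by a rule fixed at the same time. For each contrast they are the 8 largest rises and 8 largest falls that passed with groups that do not overlap (a condition not used for the interaction), up to 4 passing members of each list with the largest change, and 17 fixed genes: Hspa5, Ddit3, Xbp1, Atf4, Atf3, Trib3, Tnf, Il6, Il1b, Il12b, Il10, Il23a, Ifnb1, Cxcl10, Nos2, Tlr4 and Cd14. Gene models with no standard symbol were left out of the largest changes, and any gene outside the rule is named as chosen after its values were seen. Some genes that meet the rule are not reported here. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, only the samples of the contrast, limma without trend and with a robust fit, a minimum log2 fold change of 1, LPS-induced genes defined with tunicamycin present, and leaving out each replicate in turn. Replicate numbers are shared between groups and the labels do not say what they mark.

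The method was tested on simulated data with 200 changed genes among 10311. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1, and noise was drawn separately for each gene. At 1.5-, 2- and 4-fold, 26.9%, 80.6% and 100% were recovered for LPS against control, 37.3%, 67.2% and 100% for tunicamycin against control, and 10.4%, 46.3% and 95.5% for the interaction. False calls were 2.86% to 6.12% over the 5 contrasts. In the data 34.5% of genes passed for tunicamycin against control, far more than were changed here. The recovery rates are therefore not the power of the real comparisons. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.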

Results

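The series holds RNA sequencing of mouse bone-marrow-derived macrophages, which are bone marrow cells grown for 7 days with the growth factor M-CSF. Per its title the study asked how endoplasmic reticulum (ER) stress alters the inflammatory response. Tunicamycin, an antibiotic that blocks N-linked glycosylation and so loads the ER with unfolded protein, was given at 5 ug/ml for 3 h before lipopolysaccharide (LPS), a bacterial cell wall component sensed by the receptor TLR4, at 1 ng/ml for 3 h. The 12 libraries fell into 4 groups of 3: control, LPS, tunicamycin, and tunicamycin plus LPS. The summed FPKM per library ran from 561108 to 685010, between 9507 and 9741 genes had at least 1 FPKM, and the 10 most abundant genes took 21.8% to 25.8% of the sum. Read depth was unknown because the values are FPKM. Libraries of one group correlated with Pearson's r of 0.9726 to 0.9857 across genes, and libraries of different groups with 0.8887 to 0.9515. The first principal component held 40.1% of the variance and the second 30.3%. Control replicate 2 and replicate 3 of tunicamycin plus LPS lay apart from their groups on the next 2 components, which held 6.85% and 4.02%. On the latter, all replicates of tunicamycin plus LPS were spread, with replicate 1 at 20.52, replicate 2 at 6.561 and replicate 3 at -23.28. Levels below are FPKM as mean ± SD (n = 3), and fold changes are on the log2(FPKM + 1) scale, which understates them for low genes, with the SE of the log2 value. Coordinates are mm10 gene bodies. The labels do not say whether the replicates were separate animals or cultures, so the p-values measure the spread between these samples only.

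The first comparison asked what LPS did to otherwise untreated macrophages. Il1b, which encodes the cytokine interleukin-1 beta (chromosome 2, 129364570 to 129371139, minus strand), was 519-fold higher with LPS (log2 9.02 ± 0.15), going from 0.563 ± 0.2 to 806 ± 19.4 FPKM. Tnf, the gene of tumour necrosis factor (chromosome 17, 35199381 to 35202007, minus strand), was 193-fold higher (log2 7.59 ± 0.16), and Cxcl10, an interferon-induced chemokine gene (chromosome 5, 92346638 to 92348889, minus strand), 491-fold (log2 8.94 ± 0.23). Irg1, also called Acod1, the enzyme that makes itaconate, reached 1758 ± 113 FPKM from 2.38 ± 0.953, a 535-fold rise (log2 9.06 ± 0.18). Among the falls, Dusp6, a phosphatase gene that restrains ERK signalling (chromosome 10, 99263231 to 99267489, plus strand), dropped from 35 ± 4.56 to 3.9 ± 1.51 FPKM, 7.55-fold lower (log2 -2.92 ± 0.22).

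Of the 10311 genes tested, 1894 passed the limma test at an adjusted p under 0.05, with 1084 higher and 810 lower. Of these, 858 moved at least 2-fold. In 33.68% of genes the LPS and control libraries did not overlap, where chance gives 10%. Cytokine and chemokine genes moved as a group: 26 of 30 tested rose, 0 fell and 4 did not pass, or 27 rises adjusted over the list alone (camera adjusted p = 1.11e-31, and adjusted p = 0.0126 with an estimated correlation). Il1a rose 198-fold (log2 7.63 ± 0.18) and Cxcl1, a neutrophil attractant, 220-fold (log2 7.78 ± 0.26). Il6 rose from 0.0812 ± 0.0703 to 17.1 ± 3.98 FPKM (log2 4.04 ± 0.22), while Il12b, a subunit of interleukins 12 and 23, was more variable at 28.7 ± 19.2 FPKM with LPS (log2 4.64 ± 0.48, adjusted p = 1.35e-06). All 32 tested members of the list of NF-kB feedback and other LPS-response effectors rose, also adjusted over the list alone (camera adjusted p = 1.07e-46, and adjusted p = 0.000164 with an estimated correlation). Among them were Ptgs2, the inducible cyclooxygenase (69.9-fold, log2 6.13 ± 0.25), Socs3, a feedback inhibitor of cytokine signalling (40.1-fold, log2 5.32 ± 0.15), and Nos2, the inducible nitric oxide synthase, listed at 0 in controls and at 10.9 ± 3.45 FPKM with LPS. The type I interferon list had 34 rises, 0 falls and 8 members that did not pass of 42, or 37 rises adjusted over the list alone (camera adjusted p = 1.82e-27, and adjusted p = 0.0329 with an estimated correlation). Its members Ifit1 and Rsad2, both antiviral effectors, rose 151-fold (log2 7.24 ± 0.30) and 110-fold (log2 6.78 ± 0.32). Ifnb1, which encodes interferon beta, was listed at 0 in controls and at 3.08 ± 1.23 FPKM with LPS.

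Genes of TLR4 sensing and signalling moved both ways, with 12 rises, 2 falls and 11 not passed of 25, or 13 and 2 adjusted over the list alone (camera adjusted p = 8.19e-06, and adjusted p = 0.0329 with an estimated correlation). Cd14, the LPS co-receptor, rose 5.54-fold (log2 2.47 ± 0.09) while Tlr4 itself fell 3.32-fold (log2 -1.73 ± 0.19). Apoptosis regulators gave 7 rises, 0 falls and 14 not passed of 21, the same adjusted over the list alone, with Fas, a death receptor, 7.43-fold higher (log2 2.89 ± 0.12; camera adjusted p = 0.00051, and adjusted p = 0.02 with an estimated correlation). Inflammasome genes gave 5 rises, 0 falls and 10 not passed of 15, or 6 rises adjusted over the list alone, among them the sensor gene Nlrp3 (log2 3.04 ± 0.23; camera adjusted p = 0.0069, and adjusted p = 0.0396 with an estimated correlation). Proliferation genes gave 0 rises, 10 falls and 23 not passed of 33, or 11 falls adjusted over the list alone, for example Ccne2, a G1/S cyclin (log2 -1.22 ± 0.19). For proliferation the camera call (adjusted p = 0.00055) was lost at adjusted p = 0.311 with an estimated correlation. Antigen presentation genes had 2 rises, 0 falls and 16 not passed of 18, also adjusted over the list alone, and that call (adjusted p = 0.0265) was lost at adjusted p = 0.415 with an estimated correlation. Neutrophil markers had 3 rises, 0 falls and 3 not passed of 6, also adjusted over the list alone, with the granule gene Ngp 3.34-fold higher (log2 1.74 ± 0.26). That call (adjusted p = 0.00914) was lost at adjusted p = 0.105 with an estimated correlation.

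The remaining lists did not pass camera with LPS alone. ER chaperone and degradation genes had 3 rises, 0 falls and 35 not passed of 38, or 2 rises adjusted over the list alone, among them Herpud1, a component of ER-associated degradation (log2 2.07 ± 0.12). The ATF4/CHOP list had 8 rises, 2 falls and 24 not passed of 34, the same adjusted over the list alone, including Slc7a11, the cystine transporter (9.73-fold, log2 3.28 ± 0.20). Immediate early genes gave 8 rises, 4 falls and 5 not passed of 17, or 9 and 4 adjusted over the list alone, with Junb at log2 2.41 ± 0.09 and Jun at log2 -1.73 ± 0.17. Homeostatic macrophage genes gave 1 rise, 4 falls and 18 not passed of 23, the same adjusted over the list alone, the falls including Mertk, a receptor for dying cells (log2 -1.59 ± 0.28). Glycolysis (4 rises, 0 falls, 19 not passed), NRF2 targets (4, 2 and 14), autophagy and lysosome (2, 2 and 25), cholesterol (1, 1 and 22), N-glycosylation (1, 1 and 30) and macrophage markers (1, 1 and 8) were the others. Adjusted over the list alone these gave the same rises and falls, except 0 rises in N-glycosylation. None of 7 stromal markers passed in limma, and 0 of them had an unadjusted p under 0.05. With quantile normalization the share of rises among changed genes went from 57.2% to 48%.

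The second comparison asked what tunicamycin did without LPS. Hspa5, the ER chaperone BiP (chromosome 2, 34771970 to 34777547, plus strand), rose 11.2-fold (log2 3.49 ± 0.14), from 841 ± 73.2 to 9594 ± 2060 FPKM. Ddit3, which encodes the stress transcription factor CHOP, rose 34.5-fold (log2 5.11 ± 0.15), and Trib3, a pseudokinase gene downstream of it (chromosome 2, 152337422 to 152344032, minus strand), 85.2-fold (log2 6.41 ± 0.15). The chemokine genes Ccl2 (chromosome 11, 82035571 to 82037453, plus strand) and Ccl7, which attract monocytes, fell 27.6-fold (log2 -4.79 ± 0.15) and 16.1-fold (log2 -4.01 ± 0.13). Ccl2 went from 479 ± 115 to 16.2 ± 2.62 FPKM. C5ar1, the receptor of complement fragment C5a, fell 17-fold (log2 -4.09 ± 0.15), and Id1, an inhibitor of helix-loop-helix transcription factors, 25.4-fold (log2 -4.67 ± 0.22).

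The limma test passed 3557 of the 10311 genes, 1843 higher and 1714 lower, of which 1043 moved at least 2-fold. In 48.19% of genes the libraries of the groups did not overlap, where chance gives 10%. In the ATF4/CHOP list 31 of 34 genes rose, 1 fell and 2 did not pass, or 32 rises and 1 fall adjusted over the list alone (camera adjusted p = 2.45e-24, and adjusted p = 0.00478 with an estimated correlation). Chac1, which degrades glutathione, rose 15.2-fold (log2 3.93 ± 0.24), Ppp1r15a, which restores translation after stress, 15.5-fold (log2 3.96 ± 0.09), and Atf4 itself 6.62-fold (log2 2.73 ± 0.12). ER chaperone, folding and degradation genes gave 27 rises, 3 falls and 8 not passed of 38, or 28 and 4 adjusted over the list alone. The camera call for them (adjusted p = 2.71e-10) was lost at adjusted p = 0.252 with an estimated correlation. Herpud1 rose 55.9-fold (log2 5.80 ± 0.12), Dnajb9, a BiP co-chaperone, 8.91-fold (log2 3.15 ± 0.15), and Xbp1, a transcription factor of the unfolded protein response, 2.08-fold (log2 1.05 ± 0.09). N-glycosylation genes went both ways, with 8 rises, 7 falls and 17 not passed of 32, the same adjusted over the list alone (camera adjusted p = 0.875). Gfpt1, the first enzyme of UDP-GlcNAc synthesis, rose 2.19-fold (log2 1.13 ± 0.20) and Dad1, a subunit of the oligosaccharyltransferase, fell 2.56-fold (log2 -1.35 ± 0.13).

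Inflammatory genes also moved with tunicamycin alone. The NF-kB and LPS-effector list had 20 rises, 2 falls and 10 not passed of 32, also adjusted over the list alone (camera adjusted p = 5.91e-08, and adjusted p = 0.046 with an estimated correlation), with Nfkb2, an NF-kB subunit gene, 4.18-fold higher (log2 2.06 ± 0.11). Interferon-response genes gave 28 rises, 0 falls and 14 not passed of 42, or 29 rises adjusted over the list alone. The camera call (adjusted p = 5.91e-08) was lost at adjusted p = 0.252 with an estimated correlation. Cxcl10 rose 6.71-fold with tunicamycin (log2 2.75 ± 0.23) to 23.1 ± 5.91 FPKM, against 1767 ± 509 FPKM with LPS. Cytokine and chemokine genes were mixed, with 8 rises, 5 falls and 17 not passed of 30, also adjusted over the list alone (camera adjusted p = 0.722). Csf1, the gene of M-CSF, rose 6.25-fold (log2 2.64 ± 0.17) and Ccl4, a macrophage inflammatory protein gene, fell 6.98-fold (log2 -2.80 ± 0.14). Tnf rose 1.85-fold (log2 0.88 ± 0.16) at a level of 6.1 ± 0.537 FPKM, and Il1b was at 0.352 ± 0.16 FPKM (log2 -0.21 ± 0.15, adjusted p = 0.304). Ticam2, the adaptor TRAM of TLR4 signalling, rose 9.85-fold (log2 3.30 ± 0.14) and Cd14 fell 2.13-fold (log2 -1.09 ± 0.09), in a TLR4 list with 6 rises, 2 falls and 17 not passed of 25, also adjusted over the list alone (camera adjusted p = 0.208).

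Growth and metabolic genes fell in part. Proliferation genes had 0 rises, 21 falls and 12 not passed of 33, or 23 falls adjusted over the list alone, with Rrm2, a subunit of ribonucleotide reductase, 2.45-fold lower (log2 -1.29 ± 0.21). The camera call (adjusted p = 6.97e-09) was lost at adjusted p = 0.0954 with an estimated correlation. Cholesterol genes had 1 rise, 11 falls and 12 not passed of 24, or 1 and 12 adjusted over the list alone, with Idi1, an isomerase of the isoprenoid steps, 2.81-fold lower (log2 -1.49 ± 0.24). For cholesterol the camera call (adjusted p = 0.00167) was lost at adjusted p = 0.0802 with an estimated correlation. Glycolysis and HIF-1 targets had 3 rises, 13 falls and 7 not passed of 23, also adjusted over the list alone, with Ldha, lactate dehydrogenase, 1.74-fold lower (log2 -0.80 ± 0.09). For glycolysis the camera call (adjusted p = 0.0118) was lost at adjusted p = 0.252 with an estimated correlation. Homeostatic macrophage genes had 3 rises, 7 falls and 13 not passed of 23, or 3 and 8 adjusted over the list alone, with Cx3cr1, the fractalkine receptor, 4.71-fold lower (log2 -2.24 ± 0.26) and Msr1, a scavenger receptor, 3.91-fold (log2 -1.97 ± 0.10). For the homeostatic list the camera call (adjusted p = 0.00416) was lost at adjusted p = 0.0775 with an estimated correlation. Stromal markers had 4 rises, 0 falls and 3 not passed of 7, or 6 rises adjusted over the list alone, all at low levels. Dcn, a collagen-binding proteoglycan, went from 0.608 ± 0.471 to 10.4 ± 5.4 FPKM. For the stromal markers the camera call (adjusted p = 0.0105) was lost at adjusted p = 0.339 with an estimated correlation. Beside these falls, neutrophil markers had 0 rises, 3 falls and 3 not passed of 6, also adjusted over the list alone (camera adjusted p = 0.158), with S100a8 6.92-fold lower (log2 -2.79 ± 0.48), and macrophage markers had 1 rise, 3 falls and 6 not passed of 10, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.261), with Cd68 1.49-fold lower (log2 -0.58 ± 0.08).

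Apoptosis regulators split, with 6 rises, 4 falls and 11 not passed of 21, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.445). Gadd45a, a growth arrest gene, rose 27.8-fold (log2 4.80 ± 0.23), Bbc3, the death-promoting gene Puma, 2.8-fold (log2 1.49 ± 0.18), and Bcl2l1, the survival gene Bcl-xL, fell 6.23-fold (log2 -2.64 ± 0.11). Immediate early genes gave 5 rises and 6 falls of 17, inflammasome genes 6 and 1 of 15, NRF2 targets 6 and 5 of 20, autophagy and lysosome genes 4 and 4 of 29, and antigen presentation genes 2 and 3 of 18, none passing camera. Adjusted over the list alone the counts were the same, except 1 rise in antigen presentation. Sqstm1, an autophagy receptor and NRF2 target, rose 5.08-fold (log2 2.35 ± 0.11).

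The third comparison asked how tunicamycin before LPS changed the LPS-treated state. Il23a, which encodes the p19 subunit of interleukin-23 (chromosome 10, 128296139 to 128298752, minus strand), stood at 49.4 ± 6.72 FPKM with both agents and at 0.338 ± 0.168 FPKM with LPS, 37.6-fold higher (log2 5.23 ± 0.23). Il6 was 3.68-fold higher with both (log2 1.88 ± 0.22; 65.3 ± 13.3 against 17.1 ± 3.98 FPKM), Nos2 3.1-fold (log2 1.63 ± 0.26) and Csf1 5.77-fold (log2 2.53 ± 0.17). Il1b was 2.79-fold lower (log2 -1.48 ± 0.15; 291 ± 50 against 806 ± 19.4 FPKM), as were Socs1, a feedback inhibitor of cytokine signalling (4.3-fold, log2 -2.10 ± 0.29), and Zfp36, a destabiliser of cytokine mRNA (4.02-fold, log2 -2.01 ± 0.13). Tnf stood at 1048 ± 113 against 743 ± 62.4 FPKM, 1.41-fold higher (log2 0.49 ± 0.16, adjusted p = 0.029). For Tnf, tunicamycin plus LPS versus LPS, the adjusted p ran from 0.003 to 0.107 over the settings run. It was above 0.05 with a pseudocount of 0.1, with no filter, and without LPS replicate 1 (0.0994), LPS replicate 3 (0.0787) or replicate 1 of tunicamycin plus LPS (0.107).

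**Figure D1:**
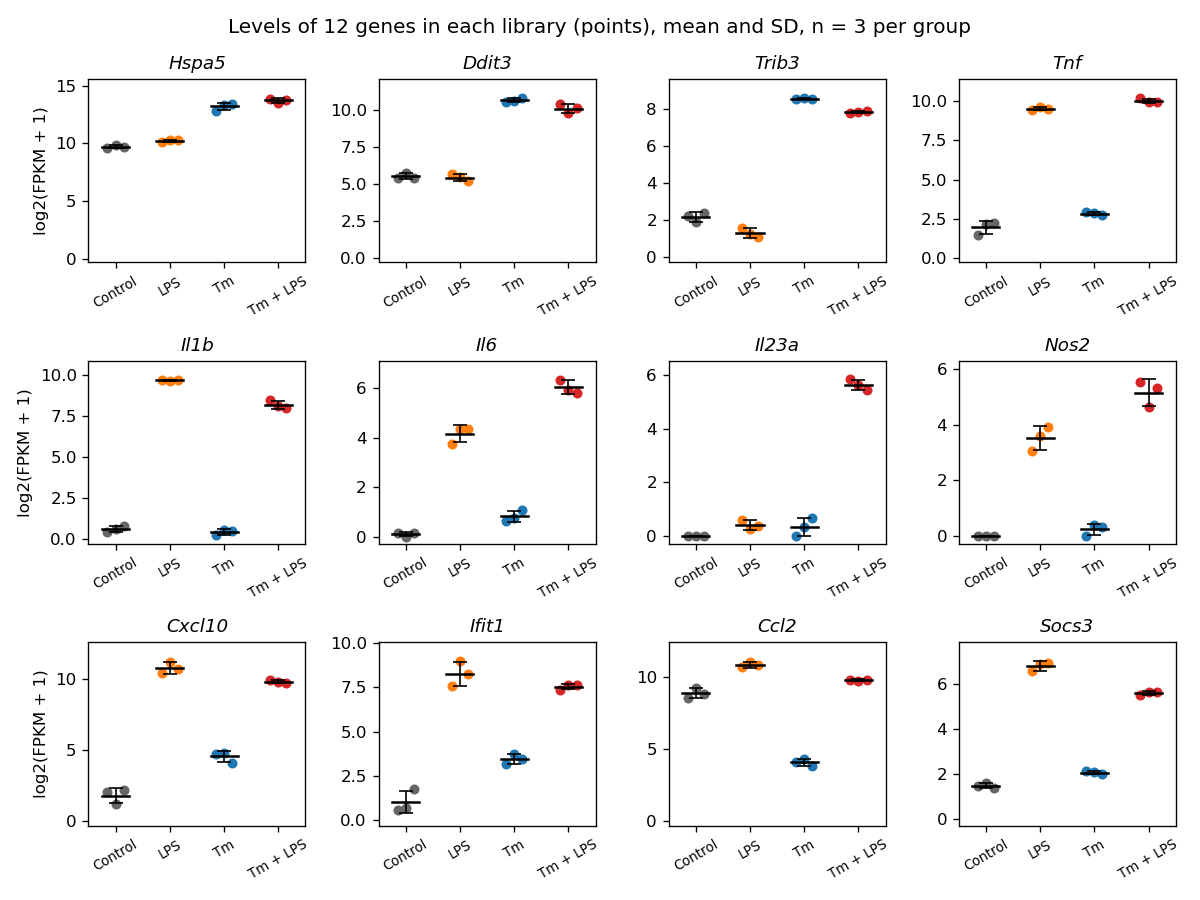
Levels of 12 genes as log2(FPKM + 1) on the vertical axis in the 4 groups on the horizontal axis; points are libraries, horizontal lines group means and error bars SD (n = 3). Il23a stands at 49.4 ± 6.72 FPKM with both agents and at 0.338 ± 0.168 with LPS, while Il1b stands at 291 ± 50 and 806 ± 19.4 FPKM.

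In this comparison 2978 of 10311 genes passed the limma test, 1419 higher and 1559 lower, with 785 at least 2-fold. In 40.3% of genes the libraries did not overlap, against 10% by chance. The stress lists rose again. In the ATF4/CHOP list 31 genes rose, 1 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 2.83e-28, and adjusted p = 0.00283 with an estimated correlation), with Trib3 93.8-fold higher (log2 6.55 ± 0.15). ER genes had 24 rises, 3 falls and 11 not passed, or 28 and 3 adjusted over the list alone, with Hspa5 11.2-fold higher (log2 3.49 ± 0.14). For the ER list the camera call (adjusted p = 4.93e-12) was lost at adjusted p = 0.246 with an estimated correlation. Across all tested genes the tunicamycin effects without and with LPS, which share no library, correlated with Pearson's r = 0.661 and Spearman's rho = 0.638; genes are not independent replicates. Of 2040 genes called in both, 1979 had the same sign, 932 higher (253.6 for independent lists) and 1047 lower (259.2), and 61 had opposite signs.

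Inflammatory lists showed no common direction here. Cytokine and chemokine genes had 9 rises, 5 falls and 16 not passed of 30, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.362), Ccl12, a monocyte attractant, being 11.9-fold lower (log2 -3.57 ± 0.58). The NF-kB and LPS-effector list had 12 rises, 11 falls and 9 not passed of 32, or 13 and 11 adjusted over the list alone (camera adjusted p = 0.992), with Cd83, an activation marker, 2.66-fold higher (log2 1.41 ± 0.12). Interferon genes had 6 rises, 9 falls and 27 not passed of 42, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.362). Irgm1, an interferon-induced GTPase, was 3.51-fold lower (log2 -1.81 ± 0.18) and Cxcl10 1.97-fold (log2 -0.98 ± 0.23). TLR4 genes had 2 rises and 4 falls of 25, inflammasome genes 4 and 4 of 15, immediate early genes 3 and 2 of 17 and apoptosis regulators 6 and 3 of 21, none passing camera. Adjusted over the list alone these were 2 and 4, 4 and 4, 3 and 3, and 7 and 4. Casp4, the sensor of cytosolic LPS, was 3.09-fold higher (log2 1.63 ± 0.19) and Egr2, a zinc finger transcription factor, 3.93-fold lower (log2 -1.97 ± 0.28).

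Among 538 genes that LPS raised at least 2-fold, 123 (22.9%) were lower and 113 (21%) higher with tunicamycin plus LPS than with LPS, and 302 did not pass. Simulations in which tunicamycin had no effect, with the LPS libraries shared by both comparisons as here, gave at most 1 gene in each direction, and independent lists would share 81.3 and 74. Defined instead from tunicamycin plus LPS against tunicamycin, 374 genes were LPS-induced, of which 71 (19%) were lower and 114 (30.5%) higher with both agents than with LPS. The definition from LPS against control selects on high LPS libraries, which leans to lower genes, and the other selects on high libraries with both agents, which leans to higher genes; the size of this lean for genes that tunicamycin does change was not simulated. The balance of lower and higher genes therefore depends on the definition. Of the 320 genes that LPS lowered at least 2-fold, 38 were lower still and 77 higher. Selecting on low LPS libraries leans to higher genes, and no simulation was made for these counts.

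Proliferation genes had 1 rise, 19 falls and 13 not passed of 33, or 1 and 22 adjusted over the list alone, with Cdk1, the mitotic kinase, 2.48-fold lower (log2 -1.31 ± 0.13). For proliferation the camera call (adjusted p = 2.14e-09) was lost at adjusted p = 0.14 with an estimated correlation. Cholesterol genes had 1 rise, 10 falls and 13 not passed of 24, also adjusted over the list alone, with Idi1 2.28-fold lower (log2 -1.19 ± 0.24). For cholesterol the camera call (adjusted p = 0.0219) was lost at adjusted p = 0.18 with an estimated correlation. Homeostatic macrophage genes had 1 rise, 9 falls and 13 not passed of 23, or 1 and 10 adjusted over the list alone, with Msr1 5.09-fold lower (log2 -2.35 ± 0.10). For the homeostatic list the camera call (adjusted p = 0.00696) was lost at adjusted p = 0.114 with an estimated correlation. Beside these falls, neutrophil markers had 0 rises, 4 falls and 2 not passed of 6, also adjusted over the list alone, with S100a8 26.5-fold lower (log2 -4.73 ± 0.48; 5.69 ± 4.74 against 138 ± 44.3 FPKM). For the neutrophil markers the camera call (adjusted p = 0.0103) was lost at adjusted p = 0.159 with an estimated correlation. Macrophage markers had 0 rises, 4 falls and 6 not passed of 10 and stromal markers 2 rises, 0 falls and 5 not passed of 7, both the same adjusted over the list alone (camera adjusted p = 0.362 and 0.102). Glycolysis gave 3 rises and 7 falls of 23, N-glycosylation 7 and 7 of 32, NRF2 targets 6 and 5 of 20, autophagy and lysosome 3 and 7 of 29, and antigen presentation 1 and 4 of 18, none passing camera. Adjusted over the list alone the rises were 3, 8, 8, 3 and 1 and the falls the same.

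A further comparison asked what LPS did in cells that had received tunicamycin. How long the cells with tunicamycin alone were exposed is not given, so time after tunicamycin may differ too. Il1b rose 215-fold (log2 7.75 ± 0.15), Tnf 147-fold (log2 7.20 ± 0.16) and Ccl4 147-fold (log2 7.20 ± 0.14), the last from 45.3 ± 11.5 to 6681 ± 325 FPKM. Il23a rose 39.7-fold (log2 5.31 ± 0.23), from 0.285 ± 0.296 FPKM, and Il6 37.2-fold (log2 5.22 ± 0.22). Il27, a cytokine subunit gene, was listed at 0 with tunicamycin and at 75.2 ± 27.5 FPKM with both. Slc40a1, the iron exporter ferroportin, fell 4.68-fold (log2 -2.23 ± 0.13).

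The limma test passed 1618 of 10311 genes, 896 higher and 722 lower, with 602 at least 2-fold, and the libraries did not overlap in 31.73% of genes, against 10% by chance. Cytokine and chemokine genes had 25 rises, 0 falls and 5 not passed of 30, also adjusted over the list alone (camera adjusted p = 1.14e-38, and adjusted p = 0.00663 with an estimated correlation). The NF-kB and LPS-effector list had 30 rises, 0 falls and 2 not passed of 32, or 31 rises adjusted over the list alone (camera adjusted p = 1.14e-39, and adjusted p = 0.000304 with an estimated correlation), with Ptgs2 63.8-fold higher (log2 6.00 ± 0.25). Apoptosis regulators had 8 rises, 3 falls and 10 not passed of 21, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00186, and adjusted p = 0.0383 with an estimated correlation). Bcl2l1 rose 5.07-fold (log2 2.34 ± 0.11) and Bcl2a1d, another survival gene, whose near-identical paralogs can share its reads, 6.58-fold (log2 2.72 ± 0.14). Interferon genes had 23 rises, 0 falls and 19 not passed of 42, or 25 rises adjusted over the list alone, with Ifit1 16.8-fold higher (log2 4.07 ± 0.30). For interferon genes the camera call (adjusted p = 2.32e-13) was lost at adjusted p = 0.127 with an estimated correlation. TLR4 genes had 9 rises, 1 fall and 15 not passed of 25, also adjusted over the list alone, with Cd14 8.72-fold higher (log2 3.12 ± 0.09). For TLR4 genes the camera call (adjusted p = 0.00184) was lost at adjusted p = 0.127 with an estimated correlation.

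Immediate early genes had 8 rises, 1 fall and 8 not passed of 17, or 12 and 2 adjusted over the list alone, with Ier3 3.04-fold higher (log2 1.60 ± 0.15). For immediate early genes the camera call (adjusted p = 3.26e-05) was lost at adjusted p = 0.0569 with an estimated correlation. Glycolysis had 6 rises, 0 falls and 17 not passed of 23, or 7 rises adjusted over the list alone, with Hk2, a hexokinase, 2.6-fold higher (log2 1.38 ± 0.19). For glycolysis the camera call (adjusted p = 0.00247) was lost at adjusted p = 0.132 with an estimated correlation. Proliferation genes had 0 rises, 12 falls and 21 not passed of 33, or 1 and 14 adjusted over the list alone, with Plk1, a mitotic kinase, 1.89-fold lower (log2 -0.92 ± 0.19). For proliferation the camera call (adjusted p = 3.79e-05) was lost at adjusted p = 0.174 with an estimated correlation. The ATF4/CHOP list had 6 rises, 3 falls and 25 not passed of 34, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.107), with Gdf15, a stress-induced cytokine, 5.14-fold higher (log2 2.36 ± 0.15) and Trib3 1.65-fold lower (log2 -0.72 ± 0.15). ER genes had 4 rises, 1 fall and 33 not passed of 38, also adjusted over the list alone (camera adjusted p = 0.186). Inflammasome genes gave 3 rises and 2 falls of 15, NRF2 targets 7 and 1 of 20, N-glycosylation 3 and 1 of 32, cholesterol 0 and 1 of 24, autophagy and lysosome 1 and 3 of 29, homeostatic genes 0 and 4 of 23, antigen presentation 1 and 0 of 18, macrophage markers 1 and 0 of 10 and neutrophil markers 1 and 0 of 6, none passing camera. Adjusted over the list alone, inflammasome genes gave 4 and 2, NRF2 targets 7 and 2, antigen presentation 0 and 0, and the others the same; 0 of 7 stromal markers passed in limma or had an unadjusted p under 0.05. LPS effects without and with tunicamycin, which share no library, correlated with r = 0.706 and rho = 0.495 across genes, and 892 of the 907 genes called in both had the same sign (592 higher, 94.2 for independent lists, and 300 lower, 56.72). Without tunicamycin replicate 2 the number of genes changed, tunicamycin plus LPS versus tunicamycin, was 1068. With quantile normalization the share of rises went from 55.4% to 44.9%.

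The last comparison tested whether the LPS effect differed between cells with and without tunicamycin, as an interaction on the log2 scale. The exposure of the cells with tunicamycin alone is not given, so a difference in time after tunicamycin may also enter the interaction. Il23a had an interaction of log2 4.90 ± 0.32, its rise with LPS being that much larger after tunicamycin. Ccl2 (log2 3.71 ± 0.21), Ccl7 (log2 2.93 ± 0.19) and Ccl4 (log2 2.50 ± 0.20) were also above 0, each having fallen with tunicamycin alone; Ccl2 stood at 883 ± 27.8 FPKM with both agents and 1877 ± 268 FPKM with LPS. Cxcl10 (log2 -3.73 ± 0.33), Ifit3, an antiviral effector (log2 -4.02 ± 0.49), Cd69, an early activation marker (log2 -3.76 ± 0.34), and Gpr84, a receptor for medium-chain fatty acids (log2 -3.36 ± 0.14), were below 0. Gpr84 stood at 17.6 ± 2.21 FPKM in controls, 167 ± 12.8 with tunicamycin, 572 ± 34.3 with LPS and 503 ± 19.8 with both.

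**Figure D2:**
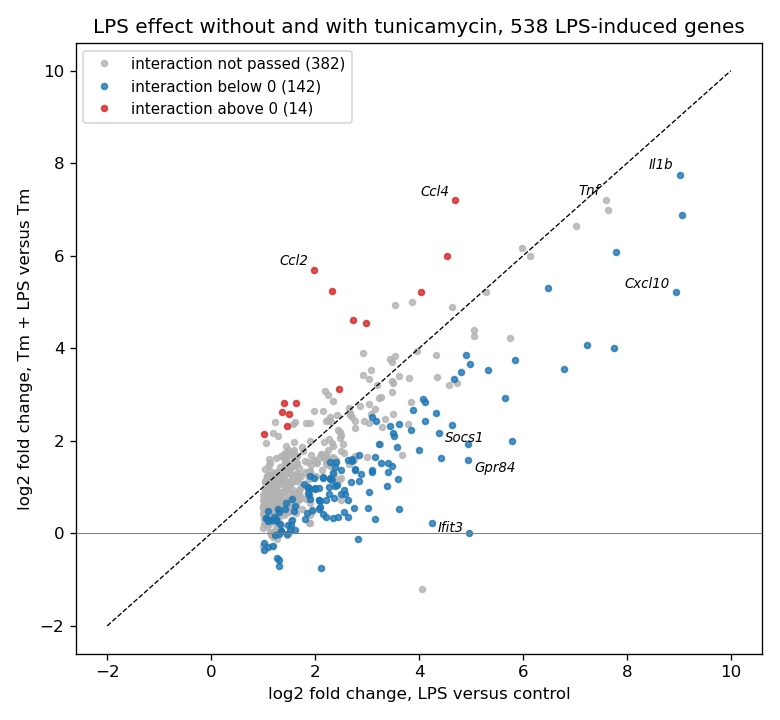
Log2 fold change of LPS against control on the horizontal axis and of tunicamycin plus LPS against tunicamycin on the vertical axis, for the 538 genes that LPS raised at least 2-fold; points are genes and the dashed line marks equal effects. Of these, 142 (blue) have an interaction below 0, 14 (red) above 0 and 382 (grey) did not pass.

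The interaction passed in 347 of 10311 genes, 145 above 0 and 202 below; 268 were at least 2-fold. Without tunicamycin replicate 3 it passed in 228, and without control replicate 2 and replicate 3 of tunicamycin plus LPS, an alternative chosen after seeing the data, in 216. The NF-kB and LPS-effector list had 0 members above 0, 18 below and 14 not passed of 32, or 2 and 21 adjusted over the list alone (camera adjusted p = 3.69e-16, and adjusted p = 0.00767 with an estimated correlation). Irg1 (log2 -2.17 ± 0.25), Ptges, a prostaglandin E synthase (log2 -2.34 ± 0.39), and Socs3 (log2 -1.79 ± 0.21) were among them. Interferon genes had 0 above 0, 14 below and 28 not passed of 42, or 24 below adjusted over the list alone. The camera call (adjusted p = 1.32e-14) was lost at adjusted p = 0.309 with an estimated correlation. Of the 142 LPS-induced genes with an interaction below 0, 112 had risen with tunicamycin alone and 59 were lower with both agents than with LPS, 29 being in both sets. Another 23 of the 142 were higher with both agents than with LPS. An interaction below 0 thus does not by itself mean a lower level with both agents. With a pseudocount of 0.1, 126 were called below 0. Cytokine and chemokine genes had 8 above 0, 3 below and 19 not passed of 30, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.119). Il1b was below 0 (log2 -1.27 ± 0.21), with an adjusted p of 0.001 to 0.266 over the settings run and the highest at a pseudocount of 0.1, and Tnf did not pass (log2 -0.39 ± 0.23, adjusted p = 0.458).

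Few stress genes passed the interaction, which passed in only 3.365% of all tested genes. ER genes had 0 above 0, 1 below and 37 not passed of 38, also adjusted over the list alone, the 1 being Herpud1 (log2 -1.55 ± 0.18), and Hspa5 had an interaction with adjusted p = 1. The ATF4/CHOP list had 0 above 0, 2 below and 32 not passed of 34, or 2 and 5 adjusted over the list alone, Ppp1r15a (log2 -1.18 ± 0.13) being below. Immediate early genes had 5 above 0 and 3 below of 17, or 6 and 5 adjusted over the list alone, with Myc, a growth transcription factor (log2 2.31 ± 0.27), and Jun (log2 2.13 ± 0.24) above. Apoptosis regulators had 2 and 2 of 21, or 3 and 4 adjusted over the list alone, with Bcl2l1 (log2 1.82 ± 0.15) above and Gadd45a (log2 -2.04 ± 0.32) below. TLR4 genes had 1 and 4 of 25, homeostatic genes 3 and 0 of 23, macrophage markers 1 and 0 of 10, autophagy and lysosome 0 and 1 of 29, inflammasome 0 and 1 of 15 and N-glycosylation 1 and 0 of 32, the same adjusted over the list alone. Glycolysis had 1 and 0 of 23 and NRF2 targets 0 and 2 of 20, or 1 and 1, and 1 and 3, adjusted over the list alone. No member passed in limma among cholesterol, proliferation, antigen presentation, neutrophil or stromal genes, where 5, 8, 2, 2 and 0 had an unadjusted p under 0.05. None of the lists in this paragraph passed camera at the preset correlation, though the neutrophil markers did so with the replicate block (adjusted p = 0.0184 against adjusted p = 0.113).

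Of the marker lists fixed for other cell types, those for dendritic, T and NK, B and plasma, erythroid and mast cells had 3, 1, 1, 0 and 1 members at the tested level and were not tested as lists. Their highest group means, chosen after the values were seen, were 114 FPKM for Bst2, which macrophages also express, 1.18 for Cd4, 1.97 for Cd79b, 0.249 for Epor and 1.75 for Hdc. Il10, the gene of an anti-inflammatory cytokine, was not tested because only 1 library reached 1 FPKM; its mean with LPS was 1.18 ± 0.574 FPKM.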

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

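The LPS-induced genes that rose with tunicamycin alone were noticed in these data before tests for them were chosen; their test bounds were set before the values they measure were seen, the split of all 12 libraries was planned before the data were examined, and the split with the main effects removed, like the simulations with no interaction, was added after the results were seen. The results listed here stood out because the LPS effect differed between cells with and without tunicamycin, by a test of that difference itself. Time after tunicamycin may also differ between the 2 groups with it, and cannot be told apart here. The test passed in 347 genes. Of 100 splits of the 12 libraries, the real one included, 2 gave as many, with 3116 in the highest other and a median of 0. These splits mix groups with large main effects, and the highest set all 6 libraries with tunicamycin against all 6 without it, so its number is that main effect and these splits do not decide about chance. With the main effects of both agents held in place and the residuals split instead, 1 of 100 splits, the real one, gave as many (highest other 49, median 0). This argues against chance for these libraries, at the smallest share that 100 splits can give. It takes the libraries as exchangeable, which the labels do not establish. Without tunicamycin replicate 3 the number of genes with an interaction was 228.

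The NF-kB feedback and other LPS-response effector list had camera adjusted p = 3.69e-16 (adjusted p = 0.00767 with an estimated correlation), and the type I interferon list adjusted p = 1.32e-14 (adjusted p = 0.309). Values below are log2 interactions, above 0 where the signed LPS effect was higher after tunicamycin, which includes genes such as Dusp6 and Jun that fell with LPS alone. The highest were Il23a 4.90 ± 0.32, Dusp6 3.90 ± 0.31, Ccl2 3.71 ± 0.21, Id1 2.94 ± 0.31, Ccl7 2.93 ± 0.19, Gna12 2.91 ± 0.69 and Dusp7 2.86 ± 0.41. Also above 0 were Ccl4 2.50 ± 0.20, Myc 2.31 ± 0.27, Jun 2.13 ± 0.24, Bcl2l1 1.82 ± 0.15, Il6 1.17 ± 0.31 and Cd14 0.66 ± 0.13. The lowest were Ifit3 -4.02 ± 0.49, Ifit2 -3.79 ± 0.54, Cd69 -3.76 ± 0.34, Cxcl10 -3.73 ± 0.33, Gpr84 -3.36 ± 0.14, Rsad2 -3.23 ± 0.45 and Ifit1 -3.17 ± 0.43. Also below 0 were Ptges -2.34 ± 0.39, Socs1 -2.22 ± 0.40, Irg1 -2.17 ± 0.25, Gadd45a -2.04 ± 0.32, Socs3 -1.79 ± 0.21, Herpud1 -1.55 ± 0.18, Ticam2 -1.46 ± 0.20, Il1b -1.27 ± 0.21, Ppp1r15a -1.18 ± 0.13, Sqstm1 -1.03 ± 0.16 and Atf3 -0.61 ± 0.15. Some of these calls were lost in part of the 20 settings: Gna12, interaction (adjusted p 0.00522 to 0.149), Atf3, interaction (0.0102 to 0.153), Socs1, interaction (0.000981 to 0.0632), Il1b, interaction (0.001 to 0.266), Cd14, interaction (0.00174 to 0.0724) and Il6, interaction (0.0243 to 0.802). Leaving out 1 library ended the Gna12 call for 7 libraries, the Atf3 call for 8 and the Il6 call for 11. With a pseudocount of 0.1 the Il6 interaction changed sign, to log2 -0.38 (adjusted p = 0.802), and its call was lost in 15 of the 20 settings. Short gene models gave the values 4.05 for Mir8112 and -4.96 for Mir6244. Mir8112 (131 bp) was at 15.7, 14.7 and 16.1 FPKM in controls and listed at 0 elsewhere, and Mir6244 (117 bp) at 44.1, 23.7 and 26.3 FPKM with LPS and listed at 0 elsewhere.

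A pattern beside the negative interactions is that 256 of the 538 LPS-induced genes rose with tunicamycin alone (96.2 for independent lists) and 40 fell (89.4). Of the 142 LPS-induced genes with a negative interaction, 83 rose with tunicamycin alone without being lower with both agents than with LPS. Another 30 were lower with both only, and 29 did both. Of the 142, 23 were higher with both agents than with LPS. A negative interaction needs a rise with tunicamycin alone or a fall with both by arithmetic. Selecting on a high LPS effect also favours a negative sign. Simulations with no interaction gave at most 1 LPS-induced gene with a negative call. The mean interaction over the LPS-induced genes was log2 -0.0946 in these simulations, against -0.682 in the data. The lean for genes that do have an interaction was not simulated. In 100 simulations with no tunicamycin effect and noise drawn separately for each gene, at most 1 LPS-induced gene was called higher with tunicamycin alone. Control libraries shared by both comparisons therefore did not give such calls by themselves there. How far shared controls add to the overlap among genes that tunicamycin does change was not simulated and stays open. The tables argue against the pseudocount, since 253 of the 256 genes were also called with a pseudocount of 0.1. Endotoxin in the tunicamycin preparation stays open: Spearman's rho between the LPS and tunicamycin effects over the LPS-induced genes was 0.227 (95% bootstrap interval 0.147 to 0.309; mean -0.0608 in the simulations with no tunicamycin effect, where the shared controls also enter), between the bounds set for and against it, and no group separates the preparation from the drug. The bootstrap interval of rho was drawn over genes, which are not independent, and leaves out the spread between libraries. Other values went both ways. The 50 most LPS-induced genes had a median tunicamycin log2 fold change of 1.2 (33 rose, 2 fell), against 0.49 for the other LPS-induced genes. Il1b did not pass with tunicamycin alone, and Ccl2, Ccl7, Ccl4 and Cd14 were among the LPS-induced genes that fell with it. Signalling from the stressed ER to inflammatory genes may also raise the LPS-induced genes and was not tested apart from endotoxin.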

How the results depend on the processing

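The setting without Tm_LPS replicate 3 and Control replicate 2 was added after seeing the data; the others were planned. Of 407 named gene results 382 were called, 322 of them in every setting run, and of 25 not called 18 stayed so. A minimum log2 fold change of 1 left 858 (LPS versus control), 1043 (tunicamycin versus control), 785 (tunicamycin plus LPS versus LPS) and 602 genes (versus tunicamycin), and 67 lower and 42 higher LPS-induced genes, by its own construction. LPS-induced genes lower with tunicamycin plus LPS than with LPS numbered 71 of 374 (19%) when defined from Tm_LPS minus Tm, against 123 of 538 (22.9%), a smaller pool that selects on the Tm_LPS libraries by construction. With each replicate left out, genes changed, tunicamycin plus LPS versus tunicamycin, numbered 1068 (without Tm replicate 2) to 1655, and genes with an interaction 228 (without Tm replicate 3) to 352, or 216 without Tm_LPS replicate 3 and Control replicate 2; the cause was not tested. With the replicate number as a block (replicate block) the numbers were 1858, 3552, 2993, 1628 and 348, and 0 of 18 pairs of libraries with the same number correlated above 0.1 after removing group means (-0.0391 to 0.0945). The number of gene lists called went from 34 to 13 with the correlation between genes estimated from the data, 37 with the replicate block and 36 with a pseudocount of 0.1. The estimates ran from -0.0333 (inflammasome) to 0.432 (ER list), against the preset 0.01. The homeostatic list lost its calls at an estimate of 0.00764, so a higher estimate does not account for every loss. Beyond this the cause was not tested. The block added stromal markers, tunicamycin plus LPS versus LPS (adjusted p = 0.0388, 0.102 without it), homeostatic genes, tunicamycin plus LPS versus tunicamycin (0.0483, 0.0526), and neutrophil markers, interaction (0.0184, 0.113). The pseudocount added homeostatic genes (0.0392) and NRF2 targets (0.0489, 0.0526), both tunicamycin plus LPS versus tunicamycin. Results that changed sign passed under neither setting, except the Il6 interaction. Lists: antigen presentation, tunicamycin versus control, 0.985 with the replicate block, and homeostatic and alternatively activated macrophage genes, interaction, 0.984 with the replicate block and 0.874 with a pseudocount of 0.1 (adjusted p). Genes (log2), tunicamycin plus LPS versus tunicamycin: Xbp1 0.00091 with median-of-ratios scaling and -0.034 to 0.047 with a replicate left out, Atf4 -0.10 with quantile normalization. Interaction: Hspa5 0.0052 with median-of-ratios scaling, 0.29 with quantile normalization and -0.19 to 0.11 with a replicate left out; with quantile normalization Xbp1 -0.043 and Trib3 -0.21; with a pseudocount of 0.1 Il6 -0.38 (adjusted p = 0.802, the range over settings being 0.0243 to 0.802, with the call lost in 15 of 20) and Il12b -1.46, the latter -0.42 to 0.83 with a replicate left out. Ifnb1 ran from -0.86 to 0.40 in both the interaction and tunicamycin plus LPS versus LPS with a replicate left out, and was 0.40 without Tm_LPS replicate 3 and Control replicate 2. Ddit3, LPS versus control, ran from -0.22 to 0.016, and was 0.00083 without Tm_LPS replicate 3 and Control replicate 2. For these the cause was not tested. The Il6 interaction was log2 1.17 ± 0.31 (adjusted p = 0.0496) as reported. Depth is unknown, so what it limits was not assessed.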

Other observations

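The neutrophil marker test, its bounds included, was chosen after the values were seen, and its upper bound was raised from 3 to 5 standard errors once the value of 3.03 was known; the ribosomal protein genes were chosen after their values were seen, and the split test of lists with an estimated correlation was added after that with the preset one. Mir546 (121 bp), chosen after its values were seen, was at 0, 28.9 and 0 FPKM in controls, 42.9, 18.9 and 38 with tunicamycin, 36.1, 17.3 and 48.3 with both agents, and listed at 0 with LPS.

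With tunicamycin plus LPS, 4 of 6 neutrophil markers were lower than with LPS and 2 did not pass (camera adjusted p = 0.0103, lost at adjusted p = 0.159 with an estimated correlation). Fewer cells of the neutrophil lineage would lower all of its markers by a like factor. The log2 FPKM ratio was -5.32 for S100a8 and -3.2 for S100a9, which activated macrophages also express, against -1.84 for Ngp and -2.09 for Ltf. The difference between the pairs was -2.3, or 3.03 standard errors, which the bound of 3 would have counted against this explanation and the bound of 5 leaves open. As both bounds were set after the values were seen, the test decides neither way. Fewer such cells and regulation of S100a8 and S100a9 in the macrophages were not told apart.

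Ribosomal protein genes fell with tunicamycin: 63 of 81 were lower, 0 higher, with a median log2 fold change of -0.519 (-0.523 with median-of-ratios scaling, which changed few calls). With LPS, 36 were lower and 1 higher with tunicamycin than without it, 20 were higher and 0 lower with LPS after tunicamycin, and for LPS alone limma passed 0, with 1 at an unadjusted p under 0.05. The tables argue against a few genes taking most of the FPKM as the cause. The 10 most abundant genes took 25.3% to 25.6% of the sum in controls and 25.5% to 25.7% with tunicamycin. With quantile normalization the median was -0.269 (95% interval -0.401 to -0.167), only just past the bound set against this cause. Median-of-ratios factors were 1.012 to 1.017 in all 12 libraries. That scaling could therefore change little, and its median of -0.523 does not bear on this cause. Why quantile normalization gave a smaller fall than -0.519 was not tested. Gene length bias stays open: genes matched on length and FPKM also fell, by a median of -0.29, and the median difference was -0.163 (-0.36 to -0.0476), between the bounds set for and against it. Both intervals in this paragraph were drawn over genes, which are not independent, and leave out the spread between libraries. A lower output of ribosomes under ER stress may be a biological explanation and was not tested.

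For the other comparisons 6 libraries make 10 splits, too few for a share under 0.05. Every split but the real one mixes libraries of both groups. The difference between the groups then enters the residuals, so low numbers follow by construction. In each, 1 split, the real one, gave a number as large: LPS versus control 1894 (highest other 0), tunicamycin versus control 3557 (0), tunicamycin plus LPS versus LPS 2978 (0), tunicamycin plus LPS versus tunicamycin 1618 (1), and LPS-induced genes lower (123; 0) or higher (113; 0) with both agents than with LPS. For the number of gene lists called at the preset correlation, 32 of 100 splits gave at least the real 34 (highest other 45, median 27). With an estimated correlation 1 of 100 splits, the real one with 13, gave as many (highest other 5, median 0). Both use splits of all 12 libraries, which carry the treatment effects into the groups and the residuals, so neither decides about chance.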
